A study of Mus musculus with 14 samples.

How the data were processed

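CD4 T cells from mouse spleen, peripheral and mesenteric lymph nodes were cultured under Th17, Treg or Th1 polarising conditions with or without acetate, and total RNA was hybridised to Affymetrix arrays, per the labels' protocols; those of the Treg and Th1 samples name the Mouse 430 2.0 type. The deposited values are 1 signal intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes; its version and target value are not given in the sources used here. Present and absent calls were not used here, so no probe set was tested for signal above background, and the number of arrays limits the precision. All 14 arrays entered through the group given in their labels, and no column of the table was left out.

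Of 45101 probe sets 34958 carry 1 gene symbol in the platform annotation, 932 carry several and 9211 are unnamed in it; the 64 array controls are among these and were left out of the gene tests. Symbols were looked up through the Entrez identifier in a RefSeq gene table, which matched 34754 probe sets and changed 0. Probe sets with several symbols or none were left out of the gene tests. Each of 18193 genes was represented by its probe set with the highest mean log2 value over the 14 arrays, and genes at or above the 40th percentile of these means (a mean log2 of 3.60, or a signal of about 9.10) were tested, 10916 in all. Of these, 6713 had several probe sets. Among genes called in the Th17, Treg and Th1 acetate comparisons, 0 had another probe set called in the opposite direction, and 4 did for the mean effect. Il17f and Ffar3 had no probe set with a single symbol and were not analysed here.

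Signals were transformed as log2(signal + 3), where 3 is the 25th percentile of all values in the table. A log2 difference is therefore on that scale and understates the change of genes with low signals. All arrays were fitted together in limma 3.58.1 (R 4.3.3) with 6 group means and no covariates, which left 8 residual degrees of freedom, and eBayes was run with a trend. Contrasts were acetate minus control in each subset, their mean with equal weight per subset, and the 3 differences between untreated subsets. A limma F test on the differences between the 3 acetate effects asked whether they differed between subsets. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Any adjusted p given for a gene is of this kind. Where the removal of an array left 1 array in a group, that array was assumed to vary like those of the other groups.

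The design assumed that MAS5 had brought the arrays to a common scale. The deposited values showed otherwise, with trimmed means from 53.2 to 116.0. The planned fit on the signals as deposited was kept as the one reported, and quantile normalization of the log2 values, planned as an alternative, is given beside it. Labels give no scan date or batch, so a batch that coincides with a subset or treatment cannot be told apart from it. The 3-prime control of 18S ribosomal RNA had signals of 2809 to 4149 in Th17 arrays and 298 to 1576 in Th1 arrays. In Treg arrays it was 3134 in control replicate 1 and 506 to 816 in the others. The source of this difference was not tested.

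A set of 32 gene lists covered T cell subsets, metabolism, stress and growth programs, and markers of other cell types. Together they held 407 genes, of which 368 were named on the array. Lists with at least 3 members tested were tested against all other genes with camera, with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. The same test with the correlation estimated from the arrays, and fry, which asks whether a list's genes move on balance one way, were run as alternatives. Only the Th17 markers in the untreated Th17 cultures, against Th1 and against Treg cultures, held with an estimated correlation among the list results given. Counts adjusted over the list alone used the members' p-values only. All counts of list members come from the signals as deposited and were not made after quantile normalization. They therefore include any shift of all genes between arrays.

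Groups, tests, lists, alternatives (save those named as chosen later) and the rule for named genes were set before the data were examined. The rule took, per acetate contrast, the 10 largest called log2 differences in each direction among genes whose acetate arrays all lay beyond all control arrays (for the mean effect, whose 3 subset differences shared their sign). It took the 5 largest in each direction between untreated subsets and the 10 smallest p-values for the difference between subsets. A fixed set of lineage genes (Il17a, Ifng, Tbx21, Foxp3, Il10, Il2, Gata3 and Il4) and acetate genes (Ffar2, Acss1 and Acss2) was added for every contrast, and up to 4 members of lists that passed or held a called gene; not all of the latter are named. Cell type marker genes named with their signals, and gene families, were chosen after their values were seen.

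The fit was tested on simulated data with the spread of the real arrays, in which 200 of 10916 genes were changed. For the Th17 comparison it recovered 21% of the genes changed by a log2 of 1 and 87% of those changed by 2, with 4 false among 112 calls. For the Treg comparison it recovered 9% and 67%, with 3 false among 79 calls. Simulated values were drawn independently for each gene and array, without brightness differences between arrays. These counts therefore do not measure false calls that an unequal scale of the real arrays could cause. Alternatives were other pseudocounts (1 and the 50th percentile), no filter or one at the 60th percentile, quantile normalization, median scaling, every probe set or the mean of all probe sets of a gene, eBayes without trend, array weights, the replicate number as a block, a fit of only the groups compared, an adjusted p under 0.10, a log2 difference of at least 1, and removal of each array in turn. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.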

Results

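Expression was measured in CD4 T cells from mouse spleen and lymph nodes after culture under Th17, Treg or Th1 polarising conditions, with or without acetate at 10 mM. Acetate is a short chain fatty acid made by gut bacteria. All cultures received IL-2, the Th17 and Treg cultures TGF-beta, the Th17 cultures in addition inflammatory cytokines that include IL-6 and IL-23, and the Th1 cultures IL-12. There were 3 control and 3 acetate arrays of Th17 cultures, and 2 arrays of each kind for Treg and for Th1 cultures, 14 in all. The protocols of the treated Treg and Th1 samples name acetone at 10 mM, whereas the design text names sodium acetate for every subset; these samples are called acetate samples here. The protocols give 5 days of culture and the design text 6 to 7 days. Nothing states whether the arrays of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. After quantile normalization, arrays of the same group correlated across genes at r = 0.940 to 0.983 over 10 pairs. Control with acetate arrays of the same subset correlated at 0.890 to 0.947 over 17 pairs. Genes are not independent replicates. On the first principal component of the quantile-normalized values, which held 28.5% of the variance, all 7 control arrays lay below 0. All 7 acetate arrays lay above it.

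The deposited signals did not share a common scale. Their trimmed mean ranged 2.18-fold, from 53.2 in Th1 control replicate 2 to 116.0 in Th17 control replicate 1. For this reason the split of higher and lower calls after quantile normalization stands beside the count of each comparison. The median log2 difference of all 10916 genes tested was -0.29 for acetate in Th17, -0.13 in Treg and 0.23 in Th1 cultures, -0.06 for the mean of the 3 subsets, 0.62 for untreated Th17 against Th1, 0.19 for Treg against Th1 and 0.41 for Th17 against Treg cultures. After quantile normalization it lay between -0.01 and 0.03 in all of these.

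**Figure D1:**
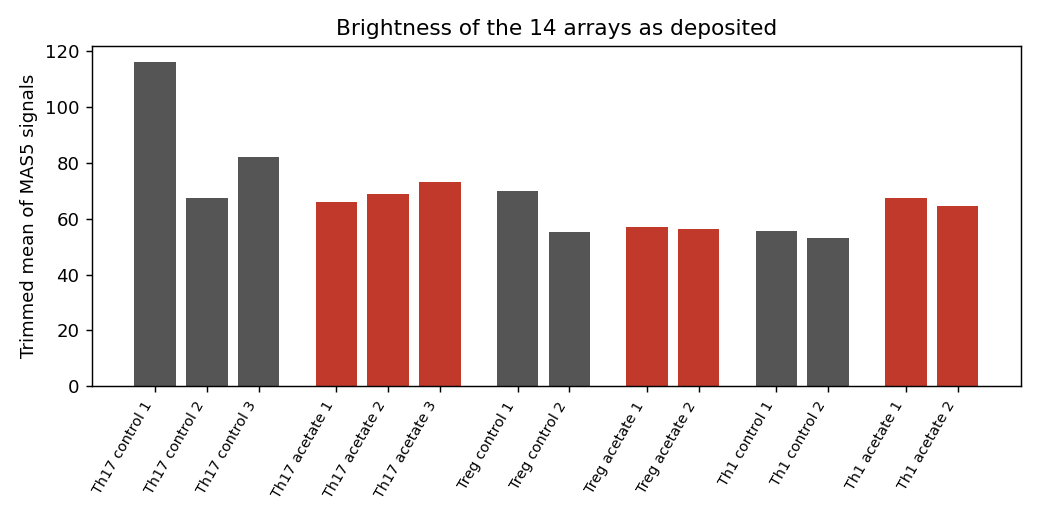
The trimmed mean of the MAS5 signals is plotted for each of the 14 arrays, with control arrays in grey and acetate arrays in red. Th17 control replicate 1 stands at 116.0, and the lowest array, Th1 control replicate 2, at 53.2.

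The untreated subsets were compared as a check of the labels and as a scale for the acetate effects. Their control arrays also serve the acetate comparisons, so a deviation of a control array enters both. Untreated Th17 cultures expressed the cytokine gene Il17a at a mean signal of 866 (SD 318, n = 3) against 7.74 (SD 2.82, n = 2) in Th1 cultures, a log2 difference of 6.31 ± 0.36 (SE, adjusted p = 7.12e-11). The Th1 mean lay under 9.10, the level at which genes were left out, so the size of this difference depends on the pseudocount. Ccr6, the chemokine receptor of Th17 cells, its ligand gene Ccl20, the gut homing receptor gene Gpr15 and Il2 were higher by 5.35, 6.70, 6.57 and 5.68. The chemokine gene Ccl5 and the death ligand gene Fasl fell by 4.05 and 3.59, Ms4a4c, the interferon target Usp18 and the granzyme gene Gzme by 3.50, 3.14 and 3.12. The acetate receptor gene Ffar2 was lower in Th17 than in Th1 cultures by a log2 difference of -2.56 ± 0.41 (adjusted p = 2.3e-04), at 28.4 against 179. Foxp3, the lineage factor of Treg cells, was higher by 2.97 and Il10 by 3.21, and Tbx21, the lineage factor of Th1 cells, differed by -2.01. Il10 did not pass without Th1 control replicate 2 (adjusted p = 0.063), nor Tbx21 without Th1 control replicate 1 (adjusted p = 0.065). Ifng (-1.02), Il4 (1.15), Gata3 (-0.03), Acss1 (0.58) and Acss2 (0.24) did not pass.

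All 10 Th17 markers tested were higher in Th17 than in Th1 cultures, also adjusted over the list alone (camera adjusted p = 6.03e-15; adjusted p = 0.025 with an estimated correlation). Of 18 Th1 markers 2 were higher and 8 lower (3 and 9 adjusted over the list alone; adjusted p = 2.75e-14, adjusted p = 0.19 with an estimated correlation and 0.11 with fry). Of 15 Treg markers 11 were higher and none lower, 11 also adjusted over the list alone (adjusted p = 0.0016; adjusted p = 0.76 with an estimated correlation). Limma called 3025 genes, 2906 higher and 119 lower, and after quantile normalization 721, of which 326 were higher and 395 lower. The count was 782, 5034 and 1537 without Th17 control replicates 1, 2 and 3, and 1786 and 486 without Th1 control replicates 1 and 2.

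Untreated Treg cultures expressed Foxp3 at 303 (SD 11.9, n = 2) against 10.9 (SD 1.60, n = 2) in Th1 cultures, a log2 difference of 4.46 ± 0.46 (adjusted p = 1.6e-06). Gzma, which encodes a granzyme, was higher by 4.75, the carbonic anhydrase gene Car2 by 4.44, and Bambi-ps1 and Ifit1bl1 by 4.99 and 4.97. Ermn, the cytokine genes Il24 and Il21, and the serpin gene Serpinb5 had log2 differences of -5.30, -4.73, -3.81 and -4.49, and its relative Serpinf1 was lower too (adjusted p = 4.93e-05). Serpinb5 did not pass when its probe sets were averaged (adjusted p = 0.079). Ffar2 was lower here too, by -2.71 ± 0.45 (adjusted p = 9e-04), at 24.6 against 179. Gata3, the lineage factor of Th2 cells, was higher by 2.44 and Acss1, which encodes a mitochondrial enzyme that activates acetate, by 2.33. Without Treg control replicate 1 their adjusted p was 0.17 and 0.14, and without Th1 control replicate 1 it was 0.11 and 0.14. Ifng (-0.43), Tbx21 (-0.47), Il17a (-0.68), Il10 (1.10), Il2 (1.66), Il4 (0.21) and Acss2 (0.50) did not pass; without Th1 control replicate 1 the adjusted p of Il10 was 0.0013 and that of Il2 7.1e-04.

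Of 15 Treg markers 6 were higher in Treg than in Th1 cultures and none lower, 6 also adjusted over the list alone (adjusted p = 2.78e-04; adjusted p = 0.54 with an estimated correlation). Of 14 glycolysis genes 2 were lower (7 adjusted over the list alone; adjusted p = 1.92e-09), of 12 hypoxia genes 3 were lower (5 adjusted over the list alone; adjusted p = 4.92e-08), and of 14 interferon response genes 3 were higher (12 adjusted over the list alone; adjusted p = 3.79e-06). For these 3 lists the adjusted p was 0.34 with an estimated correlation. With fry, the Treg markers had an adjusted p of 0.10, glycolysis of 0.11, hypoxia of 0.30 and the interferon response of 0.095. Limma called 266 genes, 204 higher and 62 lower, and after quantile normalization 545, with 311 higher and 234 lower. The count was 72 and 110 without Treg control replicates 1 and 2, 140 without Th1 control replicate 1, and 428 and 412 without Th1 acetate replicates 1 and 2.

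Against untreated Treg cultures, untreated Th17 cultures were higher in Il17a by 6.99 ± 0.36 (adjusted p = 7.49e-12; signal 866 against 4.03), in Il21 by 6.80, in Il24 by 5.48, in the protease inhibitor gene Timp1 by 5.84, in Crispld2 by 7.44 and in Il2 by 4.02. Ifit1bl1, Ccl5, Eomes, which encodes a T-box factor of cytotoxic T cells, the integrin gene Itgb3 and Pdlim4 had log2 differences of -5.40, -5.30, -4.45, -4.30 and -4.20, and Gata3 one of -2.47. Foxp3 (-1.49), Il10 (2.11), Tbx21 (-1.54) and Acss1 (-1.75) passed in the fit over all arrays. Their adjusted p was 0.087, 0.07, 0.19 and 0.097 without Treg control replicate 1, and 0.2, 0.22, 0.2 and 0.052 without Treg control replicate 2. Without Th17 control replicate 2 the adjusted p of Foxp3 was 0.057 and that of Tbx21 0.14, without Th17 control replicate 1 that of Il10 was 0.17, and without Treg acetate replicate 1 that of Tbx21 was 0.05; after quantile normalization Il10 had an adjusted p of 0.15. Ifng (-0.59), Il4 (0.94), Ffar2 (0.15) and Acss2 (-0.26) did not pass.

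All 10 Th17 markers were higher in Th17 than in Treg cultures (adjusted p = 2.17e-15; adjusted p = 0.025 with an estimated correlation), as were 11 of 14 glycolysis genes (adjusted p = 1.19e-06) and 10 of 12 hypoxia genes (adjusted p = 6.61e-07). Adjusted over the list alone these counts were 10, 11 and 10, and with an estimated correlation glycolysis and hypoxia had an adjusted p = 0.41 each. Here the median of all genes tested was 0.41, so these counts too may partly follow array brightness. Of 14 interferon response genes 10 were lower (11 adjusted over the list alone; adjusted p = 3.37e-18, and adjusted p = 0.057 with an estimated correlation), and of 18 Th1 markers 1 was higher and 8 lower (1 and 9 adjusted over the list alone; adjusted p = 1.44e-13, and adjusted p = 0.15 with an estimated correlation). Limma called 1555 genes, 1327 higher and 228 lower, and after quantile normalization 1236, with 580 higher and 656 lower. The count was 805, 2837 and 884 without Th17 control replicates 1, 2 and 3, and 826 and 336 without Treg control replicates 1 and 2.

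In Th17 cultures, Il17a rose with acetate from a mean signal of 866 (SD 318) to 4493 (SD 1247; n = 3 each), a log2 difference of 2.39 ± 0.32 (SE, adjusted p = 6.53e-05). Foxp3 fell by 2.70 ± 0.37 (adjusted p = 8.12e-05), from 116 to 15.1. On the log2 scale used, the largest rises were those of Pdlim4, which encodes an actin-associated LIM protein, at 5.33 ± 0.45 (2.02 to 216), and of the metallothionein gene Mt3 at 4.38 ± 0.48 (12.5 to 281). They were followed by the serine protease gene Prtn3 (3.90), Ccl5 (3.88), Gzme (3.69), Npl (3.49), the tropomyosin gene Tpm2 (3.28), Fxyd7 (3.16), Lum (3.08) and the mucin gene Muc1 (3.07). Csf2, which encodes the cytokine GM-CSF, had the largest fall, at -3.53 ± 0.44 (425 to 33.9), followed by Prss12 (-3.31), Trib3 (-3.21), the clock gene Nr1d2 (-3.14), Chac1 (-3.12), Dhrsx (-3.04), Itgae (-2.98), Klf2 (-2.90), Stc2 (-2.80) and Nupr1 (-2.76). All 20 of these genes kept their call without any single array. In Pdlim4, Prtn3, Gzme, Npl and Muc1 the mean control signal, and in Dhrsx the mean acetate signal, lay under 9.10, the level at which genes were left out, so the size and rank of their differences depend on the pseudocount. With a pseudocount of 1 and one at the 50th percentile, Pdlim4 rose by 6.06 and 4.01 and Gzme by 4.72 and 2.33, and all 6 kept their call.

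Several fixed lists had members called in Th17 cultures. Of 16 targets of ATF4 and endoplasmic reticulum stress, 11 fell and none rose (12 fell adjusted over the list alone; camera adjusted p = 3.42e-04), among them Trib3, Chac1, Asns, which encodes asparagine synthetase (1511 to 430; -1.79), and Shmt2 of serine metabolism (-1.60). Of 15 genes of mTOR and amino acid transport, 7 fell (8 adjusted over the list alone; adjusted p = 0.0079), among them the transporter genes Slc7a1 (-1.92), Slc1a5 (-1.72), Slc3a2 (-1.40) and Slc38a2 (-1.31). Of 17 activation genes, 7 fell (9 adjusted over the list alone; adjusted p = 0.0079), among them the immediate early genes Nr4a3 (-2.62), Egr3 (-2.57) and Nr4a1 (-1.51). Of 14 ribosome biogenesis genes, 6 fell (10 adjusted over the list alone; adjusted p = 0.0086, and 0.053 without Th17 acetate replicate 2), among them Rrp9 (-1.72). Of 23 cell cycle genes, 6 rose and 1 fell, as adjusted over the list alone (adjusted p = 8.21e-05, and 0.17 without Th17 acetate replicate 1), among them the spindle checkpoint kinase gene Bub1 (1.70). Averaged over their probe sets, Shmt2 (adjusted p = 0.058), Slc38a2 (0.066) and Nr4a3 (0.071) did not pass. With an estimated correlation each of these lists had an adjusted p = 0.87.

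Markers of other subsets were called as well. Of 18 Th1 markers 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 4.95e-04). Ccl5, the granzyme gene Gzmb (1932 to 8143; 2.37) and the chemokine receptor gene Cxcr3 (1.96) were among those that rose, and the receptor gene Cxcr6 fell (-2.66). Of 15 Treg markers 1 rose and 8 fell, as adjusted over the list alone (adjusted p = 0.031; 0.053 with a pseudocount of 1, 0.07 without Th17 control replicate 2 and 0.24 without Th17 acetate replicate 1), with Foxp3, the integrin gene Itgae, Nrp1 (-2.67) and Socs2 (-1.68) among those that fell. Of 8 follicular helper markers 2 rose, as adjusted over the list alone, Cxcr5 (1.84) among them; the list passed at an adjusted p = 0.030, but not after quantile normalization (0.079), with a pseudocount of 1 (0.11) or without Th17 control replicate 2 (0.07), Th17 acetate replicate 2 (0.11), or Treg acetate replicate 1 or 2 (0.095 and 0.098). With an estimated correlation these 3 lists had an adjusted p = 0.87. The 10 Th17 markers did not move together: Il17a rose, while Il21 (1353 to 248; -2.43) and Ccl20 (-1.64) fell, and adjusted over the list alone 1 rose and 2 fell. Their median of -0.21 was negative while camera's direction was up (adjusted p = 0.51; adjusted p = 0.87 with an estimated correlation). Ccl20 did not pass without Th17 control replicates 1 (adjusted p = 0.16) and 3 (0.073) or Th17 acetate replicate 2 (0.14), nor after quantile normalization (0.068), and Il21 had an adjusted p of 0.055 when its probe sets were averaged. Of 17 secreted cytokines 4 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.45, and adjusted p = 0.87 with an estimated correlation), Il24 (1.45) rising; here too the median, at -0.24, was negative and camera's direction up.

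Genes that handle acetate or fatty acids gave mixed values in Th17 cultures. The fatty acid synthase gene Fasn fell by 1.53 ± 0.27 (889 to 303; adjusted p = 7.43e-04) and Acly, whose enzyme makes acetyl-CoA from citrate, by 0.95; of 10 genes of acetate activation and lipogenesis 2 fell and none rose (3 fell adjusted over the list alone; adjusted p = 0.45, and adjusted p = 0.87 with an estimated correlation). Slc16a1, the gene of the monocarboxylate transporter MCT1, fell by 1.15, with an adjusted p of 0.067 without Th17 control replicate 1, and the deacetylase gene Sirt1 fell by 1.96. When probe sets were averaged, Acly (adjusted p = 0.055) and Slc16a1 (0.053) did not pass. Ffar2 (-0.05), Acss1 (-0.28) and Acss2 (0.52, adjusted p = 0.28) did not pass; Acss2 had an adjusted p of 0.032 after quantile normalization. Gata3 and Il4 fell by 1.61 and 1.41. Without Th17 control replicate 1 their adjusted p was 0.11 and 0.14, and that of Il4 was 0.11 and 0.062 without Th17 acetate replicates 1 and 2. Il10 had a log2 difference of 1.32 that did not pass (adjusted p = 0.084). It passed without Th1 control replicates 1 (0.0063) and 2 (0.0059) and Th1 acetate replicates 1 (0.037) and 2 (0.039), arrays that enter only through the shared spread. Tbx21 (1.07, adjusted p = 0.10) passed after quantile normalization (0.036) and without Th17 control replicate 1 (0.037). Ifng (-0.16) and Il2 (-0.53) did not pass. Calls among markers of other cell types went both ways. The macrophage gene Cd68 rose from 24.2 to 94.4 and the CD8 T cell gene Cd8b1 from 57.0 to 150.3, but Csf1r (-0.67), Itgax (-0.73), Adgre1 (-0.43) and Cd8a (0.20) did not pass, and Kit (-1.90), Ighm (-1.53), Cpa3 (-1.61) and Klrd1 (-1.13) fell. Without Th17 control replicate 1 the adjusted p of Ighm, Cpa3 and Klrd1 was 0.087, 0.090 and 0.25. Without Th17 control replicate 3 that of Cpa3 was 0.051 and that of Klrd1 0.086, without Th17 acetate replicate 2 that of Ighm was 0.063 and that of Klrd1 0.24, and without Th17 acetate replicate 3 that of Cpa3 was 0.054. After quantile normalization it was 0.063 for Cpa3 and 0.094 for Klrd1, and with probe sets averaged 0.76 for Ighm and 0.061 for Klrd1. The natural killer cell list leaned higher although Klrd1 fell: its 5 genes had a median of 0.82, and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.15, 0.043 without Th17 acetate replicate 2, and adjusted p = 0.87 with an estimated correlation). Of its members Fcer1g (1.15), Tyrobp (1.03) and Klre1 (0.82) did not pass over all genes. Fcer1g passed without Th17 control replicate 2 (0.026), Th17 acetate replicate 2 (0.0499) or Th1 acetate replicate 1 (0.049), Tyrobp without Th17 control replicate 2 (0.031), and Klre1 without Th17 control replicate 1 (0.046) and after quantile normalization (0.016).

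Limma called 1928 genes in Th17 cultures, 467 higher and 1461 lower with acetate. After quantile normalization the split was 1275 higher and 945 lower of 2220, with 1385 genes called in both fits. Without Th17 control replicate 1 there were 984 calls, without Th17 control replicate 3 there were 987, and without Th17 acetate replicate 2 there were 966.

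In Treg cultures, Il24, a cytokine gene of the IL-10 family, rose with acetate from a mean signal of 16.4 (SD 6.18) to 1429 (SD 685; n = 2 each), a log2 difference of 6.15 ± 0.43 (adjusted p = 5.52e-09). Foxp3 fell by 2.55 ± 0.46 (adjusted p = 0.0018), from 303 to 49.6. Crispld2 (4.61), Ermn (4.39), the Th1 transcription factor gene Hlx (3.96), Mt3 (3.82 ± 0.59; 22.4 to 348), Dpf1 (3.78), Gpx8 (3.73), Emp1 (3.34) and Prtn3 (3.30) rose, as did Il10, by 3.28 ± 0.65 (75.2 to 755; adjusted p = 0.0038). The largest falls were those of Ifit1bl1 (-4.79 ± 0.62; 544 to 20.7), Ifi209 (-3.94), Trim12a (-3.59), Iigp1 (-3.43), Oas1a (-3.34), Dtx4 (-3.27), Irgm1 (-3.13), Slfn1 (-3.04), Bambi-ps1 (-2.98) and Klf2 (-2.93). The call was lost for Il10 without Treg control replicate 2 (adjusted p = 0.058) and for Iigp1 (0.098) and Klf2 (0.081) without Treg acetate replicate 1; the other 17 kept it without any single array. Emp1 and Dtx4 had an adjusted p of 0.14 and 0.083 when their probe sets were averaged. The size and rank of the differences of Crispld2, Ermn, Hlx, Dpf1, Gpx8, Oas1a and Dtx4 depend on the pseudocount, since their lower group mean lay under a signal of 9.10.

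Several fixed lists had members called in Treg cultures. Of 14 glycolysis genes 6 rose and none fell (10 rose adjusted over the list alone; camera adjusted p = 5.29e-09, and adjusted p = 0.46 with an estimated correlation), among them Pgam1 (957 to 3036; 1.71), the hexokinase gene Hk2 (1.90) and the lactate exporter gene Slc16a3 (2.01). Of 12 hypoxia genes 6 rose (7 adjusted over the list alone; adjusted p = 2.14e-07, and adjusted p = 0.51 with an estimated correlation), among them the mitophagy gene Bnip3 (506 to 3019; 2.66) and the oxygen sensor gene Egln3 (2.43). Of 14 interferon response genes 6 fell (10 adjusted over the list alone; adjusted p = 1.42e-07, and adjusted p = 0.46 with an estimated correlation), among them Oas1a and Irf7 (-2.80). Of 17 secreted cytokines 4 rose (6 adjusted over the list alone; adjusted p = 7.5e-07, and adjusted p = 0.46 with an estimated correlation), with Il24, Il10 and the lymphotoxin gene Lta (341 to 2056; 2.51) among them. Hk2 had an adjusted p of 0.056 without Treg acetate replicate 1, and without Treg control replicate 2 Slc16a3 had one of 0.069 and Il10 one of 0.058. With fry, glycolysis and interferon response had an adjusted p of 0.047 each, but secreted cytokines had 0.12 and hypoxia 0.19, and no list of the next paragraph passed.

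Of 9 naive and memory T cell genes 4 fell in Treg cultures (5 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.74 with an estimated correlation), and of 17 sterol synthesis genes 3 rose, as adjusted over the list alone (adjusted p = 0.0016, and adjusted p = 0.80 with an estimated correlation). Of 15 Treg markers 1 rose and 3 fell (2 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.34; adjusted p = 0.84 with an estimated correlation). Of 10 Th17 markers 1 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.59 with an estimated correlation), with the leukotriene receptor gene Ltb4r1 rising by 2.74; after quantile normalization the list's adjusted p was 0.051. The cell cycle list passed with no member called (adjusted p = 0.016, and adjusted p = 0.84 with an estimated correlation; 0.06 without Treg acetate replicate 1 and 0.091 after quantile normalization). Of 10 CD4 T cell markers 2 fell (3 adjusted over the list alone; adjusted p = 0.031, and adjusted p = 0.80 with an estimated correlation; 0.10 and 0.073 without Treg control replicate 2 and Treg acetate replicate 1). Of 6 Th2 markers 2 rose (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.025, and adjusted p = 0.59 with an estimated correlation; 0.11 after quantile normalization, and 0.055 and 0.057 without Th17 control replicate 2 and Treg acetate replicate 1). Of 10 heat shock genes none was called (2 higher adjusted over the list alone; adjusted p = 0.046, and adjusted p = 0.80 with an estimated correlation; 0.20 after quantile normalization). The heat shock list's adjusted p was 0.061, 0.12 and 0.15 without Th17 control replicate 2, Treg control replicate 2 and Treg acetate replicate 1, and 0.054 without either Th1 acetate replicate 1 or 2. Of 13 genes of p53 and apoptosis 3 fell (5 adjusted over the list alone; adjusted p = 0.046, and adjusted p = 0.80 with an estimated correlation; 0.051 after quantile normalization, 0.050 with the replicate block and 0.052 with a pseudocount of 1). That list's adjusted p was 0.076 and 0.071 without Th17 control replicates 1 and 2, 0.071 without Treg control replicate 2 and 0.073 without Treg acetate replicate 1.

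Ffar2, the gene of the acetate receptor GPR43, rose in Treg cultures from 24.6 to 148, a log2 difference of 2.40 ± 0.45 (adjusted p = 0.0025; 0.065 without Treg acetate replicate 2). Il17a (1.15, adjusted p = 0.10, and 0.040 after quantile normalization), Acss1 (-1.44, adjusted p = 0.081, and 0.032 after quantile normalization) and Gata3 (-1.52, adjusted p = 0.090) did not pass. Acss1 passed without Th17 control replicate 1 (0.038), and Gata3 without Th17 acetate replicate 1 (0.049) and Th1 acetate replicates 1 and 2 (0.022 and 0.021). Ifng (1.22), Il4 (0.16), Acss2 (-0.10), Tbx21 (-0.20) and Il2 (-0.37) did not pass either. Limma called 550 genes, 252 higher and 298 lower; after quantile normalization it called 1363, 769 higher and 594 lower, and 546 genes were called in both. The count was 186 and 158 without Treg control replicates 1 and 2 and 109 and 190 without Treg acetate replicates 1 and 2. The log2 ratio of Gapdh signal at the 3-prime over the 5-prime end, a measure of RNA quality, was 0.29 ± 0.01 (SD, n = 2) in the Treg control and 0.04 ± 0.02 in the Treg acetate arrays, whereas that of beta-actin was 0.46 ± 0.07 and 0.42 ± 0.04. The Gapdh ratios of the Treg control arrays, 0.28 and 0.30, were the highest of all arrays, the next being 0.13 in Th1 acetate replicate 1. Glycolysis and hypoxia genes were lower and interferon response genes higher in untreated Treg than in Th1 cultures, opposite to the acetate change. Both comparisons use the same Treg control arrays, so a deviation of these arrays cannot be told apart from an acetate effect.

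In Th1 cultures, the chemokine gene Ccl9 rose with acetate from a mean signal of 14.03 (SD 12.9) to 1326 (SD 726; n = 2 each), a log2 difference of 6.41 ± 0.51 (adjusted p = 6.78e-08). Il10, whose product restrains inflammation, rose by 4.53 ± 0.65 (64.0 to 841; adjusted p = 3.54e-04), Mt3 by 4.62 ± 0.59 (89.5 to 2472) and its relative Mt4 by 4.70. The 2 Th1 control arrays had Il10 signals of 120 and 7.68, so the size of its rise is imprecise. The proton pump gene Atp6v0d2 (3.97), the perforin gene Prf1 (216 to 2842; 3.86) and Havcr2, which encodes the inhibitory receptor TIM-3 (32.8 to 382; 3.49), rose as well, as did Ccl3 (4.83), Il3 (3.69) and Ccl4 (3.57). Among the falls were those of Fam183b (-3.62 ± 0.55; 78.4 to 4.62), Dnah8 (-3.40), Mob3c (-2.81), the immunoglobulin heavy chain gene Ighm (488 to 70.7; -2.77), Vldlr (-2.65) and the carnosine synthase gene Carns1 (-2.49). Cox6b2 (-2.76), Mocos (-2.70), Dntt (-2.52) and Selenbp1 (-2.29) completed the 10 largest falls. The size and rank of the differences of Mt4, Il3, Fam183b, Dnah8 and Mob3c depend on the pseudocount, since their lower group mean lay under a signal of 9.10.

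Of these 20 genes 12 kept their call without any single array. Without Th1 control replicate 2 the adjusted p was 0.062 for Ccl3, 0.099 for Il3, 0.26 for Ccl4, 0.15 for Cox6b2, 0.15 for Mocos, 0.17 for Dntt and 0.27 for Selenbp1, and without Th1 acetate replicate 2 it was 0.051 for Vldlr, 0.32 for Cox6b2, 0.12 for Mocos, 0.082 for Dntt and 0.45 for Selenbp1. Dntt also lost its call without Th17 control replicates 1 and 2 (0.053 and 0.054), and Selenbp1 without those (0.075 and 0.079) and Treg control replicates 1 and 2 (0.051 and 0.053). After quantile normalization Ccl4 (0.062) and Selenbp1 (0.058) did not pass. Ighm, Prf1, Dnah8, Mob3c, Dntt and Selenbp1 did not pass when the probe sets of each gene were averaged (0.51, 0.080, 0.063, 0.11, 0.11 and 0.082).

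Of 18 Th1 markers 4 rose with acetate in Th1 cultures and none fell (5 rose adjusted over the list alone; camera adjusted p = 0.0071), among them Havcr2, Ccl3, Ccl4 and Ccl5 (2.94; adjusted p = 0.022, 0.17 without Th1 control replicate 2, 0.055 without Th17 control replicate 2 and 0.078 after quantile normalization; Ccl3 had 0.062 and Ccl4 0.26 without Th1 control replicate 2, and Ccl4 0.062 after quantile normalization). Of 5 natural killer cell markers 2 rose, the lectin receptor genes Klre1 (2.15) and Klrc1 (2.29), and 3 rose adjusted over the list alone (adjusted p = 0.0071, and 0.097 without Th1 acetate replicate 2). Klre1 had an adjusted p of 0.12 and 0.096 without Th1 control replicate 2 and Th1 acetate replicate 2, and Klrc1 of 0.21 without the former. Of 16 genes of the TCA cycle and fatty acid oxidation none passed over all genes and 6 rose adjusted over the list alone (adjusted p = 0.0071). Of 9 naive and memory T cell genes Klf2 fell (-2.28; 3 fell adjusted over the list alone; adjusted p = 0.0071, and 0.42 without Th1 acetate replicate 2). Klf2 itself had an adjusted p of 0.23, 0.13 and 0.050 without Th1 control replicate 2, Th1 acetate replicate 2 and Th17 control replicate 2. With an estimated correlation each of these lists had an adjusted p = 0.81.

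The 12 hypoxia genes and the 13 genes of p53 and apoptosis leaned lower in Th1 cultures with no member called over all genes (camera adjusted p = 2.66e-04 and 7.72e-04; 0.065 each without Th1 acetate replicate 2). Adjusted over the list alone no hypoxia gene passed, and of the p53 list 1 rose and 4 fell. The CD4 T cell markers (0 of 10 called, 1 lower adjusted over the list alone; adjusted p = 0.014), interferon response (0 of 14 called, also adjusted over the list alone; 0.027), heat shock (2 of 10 higher, 5 adjusted over the list alone; 0.029) and secreted cytokines (2 of 17 higher, 7 adjusted over the list alone; 0.043) passed as well. Without Th1 acetate replicate 2 these had an adjusted p of 0.097, 0.2, 0.38 and 0.083. The last 3 did not pass after quantile normalization (0.062, 0.062 and 0.070), heat shock not without Th1 control replicate 1 (0.085), and the cytokines not with a pseudocount of 1 (0.062) or without Th1 control replicate 2 (0.91) or Th17 control replicates 1 and 2 (0.11 and 0.088). With an estimated correlation each list had an adjusted p = 0.81. Ifng had a log2 difference of 2.87 ± 0.87 (1719 to 10097) that did not pass (adjusted p = 0.088). It passed without Th17 acetate replicate 1 (0.0018) or 2 (0.030), Th1 control replicate 1 (0.029) or Th1 acetate replicate 1 (0.041). Il17a (0.51), Tbx21 (0.80), Foxp3 (0.09), Il2 (1.21), Gata3 (-0.85), Il4 (-0.34), Ffar2 (-0.16; 179 and 185), Acss1 (0.16) and Acss2 (0.06) did not pass; Il2 passed without Th1 control replicate 1 (0.0032) and Gata3 without Th1 acetate replicate 1 (0.048). Limma called 223 genes, 178 higher and 45 lower, and 435 after quantile normalization, 226 higher and 209 lower, with 193 called in both; a fit of the Th1 arrays alone called 10. The count was 338 without Th17 control replicate 1, 365 without Th17 acetate replicate 1, 72 without Th1 control replicate 2, and 544 and 117 without Th1 acetate replicates 1 and 2.

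**Figure D2:**
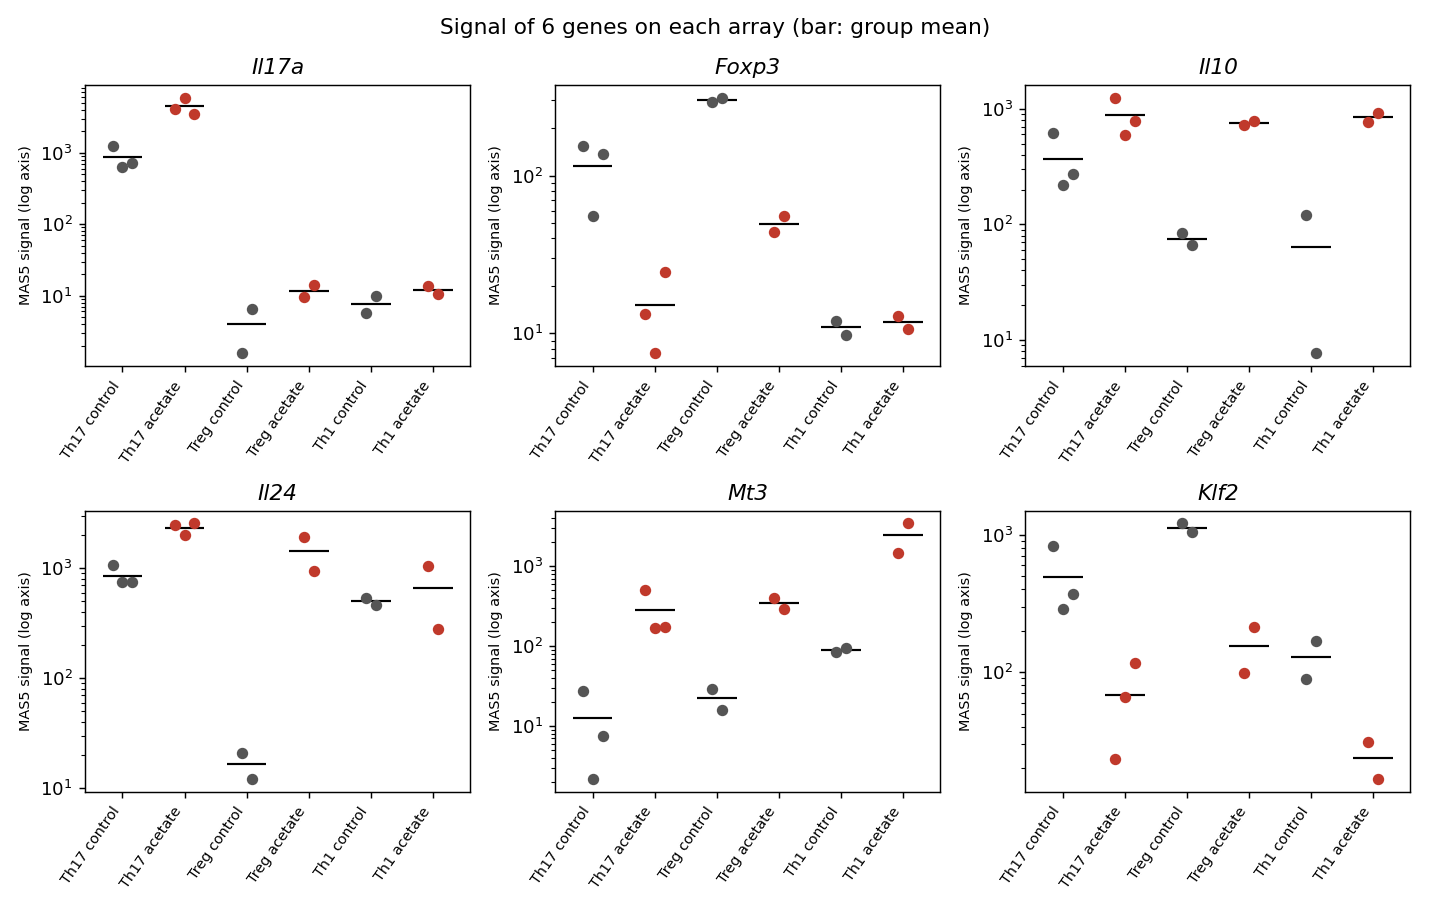
The MAS5 signal of 6 genes on each array is plotted on a log axis, with control arrays in grey, acetate arrays in red and a bar at each group mean. The Th17 acetate arrays average 4493 for Il17a against 866 in their controls, and the Treg acetate arrays average 49.6 for Foxp3 against 303.

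The mean acetate effect of the 3 subsets, each with equal weight, was then tested. Mt3 rose by 4.27 ± 0.32 (adjusted p = 9.84e-09), Ccl9 by 3.33 ± 0.28, Il10 by 3.05 ± 0.35 (adjusted p = 2.57e-06), Prtn3 by 3.05, Pdlim4 by 2.99, the granzyme genes Gzme and Gzmk by 2.68 and 2.59, Cdh17 by 2.62, the lysosomal protease gene Lgmn by 2.61 and Il24 by 2.57. Klf2, a transcription factor of quiescent T cells, fell by 2.70 ± 0.30 (adjusted p = 1.29e-06), and Mob3c (-2.56), Carns1 (-2.49), Trim12a (-2.45), the CD30 ligand gene Tnfsf8 (-2.43), Ifit1bl1 (-2.40), Slfn1 (-2.31), Dnah8 (-2.30), the cytidine deaminase gene Apobec1 (-2.28) and Xaf1 (-2.23) fell as well. All 20 of these genes kept their call without any single array. Il17a rose by 1.35 ± 0.22 (adjusted p = 1.03e-04), and Foxp3 and Gata3 fell by 1.72 ± 0.25 and 1.33 ± 0.28. By subset, Il17a and Gata3 were called only in Th17 cultures, and Foxp3 in Th17 and Treg cultures. Il17a signals stayed low in Treg (4.03 to 11.7) and Th1 cultures (7.74 to 12.1), as did Foxp3 in Th1 cultures (10.9 to 11.8). Ffar2 rose by 0.73 (adjusted p = 0.036), but its adjusted p was 0.07 without Th17 control replicate 2, 0.06 without Th17 acetate replicate 3, 0.087 and 0.064 without Treg control replicates 1 and 2, 0.14 without Treg acetate replicate 2, 0.084 without Th1 control replicate 2 and 0.17 without Th1 acetate replicate 1. Ifng (1.31) just failed (adjusted p = 0.051). It passed without Th17 control replicate 1 (0.042), Th17 acetate replicates 1, 2 and 3 (0.036, 0.0073 and 0.022), Treg acetate replicate 2 (0.037), Th1 control replicate 1 (0.013) and Th1 acetate replicates 1 and 2 (0.021 and 0.037). Tbx21 (0.56), Il2 (0.10), Il4 (-0.53), Acss1 (-0.52) and Acss2 (0.16) did not pass.

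For the mean effect, 5 of 9 naive and memory T cell genes fell (7 adjusted over the list alone; camera adjusted p = 0.0037), among them Klf2, Bach2 (-1.27) and the IL-7 receptor gene Il7r (-1.03). Of 17 secreted cytokines 6 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0037), with Il10, Il24 and Lta (1.31) among those that rose. Of 18 Th1 markers 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0038), among them Ccl5 (2.53), Hlx (1.93) and Havcr2 (1.34). Of 14 interferon response genes 6 fell (7 adjusted over the list alone; adjusted p = 0.0066), among them Oas1a (-1.75), Gbp2 (-1.57) and Irf7 (-1.45). Of 23 cell cycle genes 6 rose (7 adjusted over the list alone; adjusted p = 0.0037), and of 16 genes of the TCA cycle and fatty acid oxidation 5 rose (6 adjusted over the list alone; adjusted p = 0.015), the citrate synthase gene Cs (0.73) among them. Cell cycle genes lay above their own acetate groups in Th17 acetate replicate 1 and Th1 acetate replicate 2 (medians 1.51 and 0.94 after quantile normalization). No list was tested without both of these arrays, so the cell cycle rise may rest on them. Of 13 genes of p53 and apoptosis 2 rose and 7 fell (2 and 8 adjusted over the list alone; adjusted p = 0.015), the proapoptotic gene Bbc3 (-1.51) falling, and of 10 CD4 T cell markers 1 rose and 7 fell, as adjusted over the list alone (adjusted p = 0.015), Trat1 (-1.85) falling. With an estimated correlation each of these lists had an adjusted p = 0.72.

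Other lists passed less firmly for the mean effect. Of 15 Treg markers 2 rose, the ectonucleotidase gene Entpd1 (1.33) among them, and 7 fell, Nrp1 (-1.43) and Ikzf4 (-1.32) among them (2 and 8 adjusted over the list alone; adjusted p = 0.026, 0.06 without Th17 acetate replicate 1 and 0.063 without Th1 acetate replicate 2). Of 17 activation genes 5 fell, as adjusted over the list alone, Nr4a3 (-1.91; adjusted p = 0.056 when its probe sets were averaged) among them (adjusted p = 0.015, and 0.13 without Th1 control replicate 1). Of 17 sterol synthesis genes 3 rose, as adjusted over the list alone, Fdft1 (0.94) among them (adjusted p = 0.021, and 0.056 without Th1 control replicate 1). Of 16 targets of ATF4 and endoplasmic reticulum stress 2 rose and 6 fell, Trib3 among them (2 and 9 adjusted over the list alone; adjusted p = 0.026, 0.06 without Treg acetate replicate 2, and 0.12 and 0.11 without Th1 control replicate 1 and Th1 acetate replicate 1). Of 10 heat shock genes 3 rose, as adjusted over the list alone, Hspa1b (1.73) and Hspb1 (1.61) among them (adjusted p = 0.026, 0.090 without Th1 acetate replicate 2 and 0.13 after quantile normalization). Of 5 natural killer cell markers Klre1 rose (1.55; 2 rose adjusted over the list alone; adjusted p = 0.035, and 0.13 after quantile normalization). That list's adjusted p was 0.056 without Th17 control replicate 1, 0.052 and 0.057 without Th17 acetate replicates 1 and 3, 0.059 without Treg acetate replicate 2 and 0.090 without Th1 acetate replicate 2. Of 15 genes of mTOR and amino acid transport 1 rose and 4 fell (1 and 5 adjusted over the list alone; adjusted p = 0.048, 0.050 with a pseudocount of 1 and 0.051 with the replicate block). That list's adjusted p was 0.056 and 0.051 without Th17 control replicates 1 and 2, 0.060 and 0.051 without Th17 acetate replicates 1 and 3, 0.053 without Treg control replicate 2, 0.061 without Treg acetate replicate 2, 0.13 without Th1 control replicate 1 and 0.096 without Th1 acetate replicate 1. With an estimated correlation each had an adjusted p = 0.72. With fry, no list given as passing camera passed for the mean effect, in Th17 or in Th1 cultures (lowest adjusted p = 0.090, 0.061 and 0.27). Limma called 2303 genes, 1015 higher and 1288 lower, and after quantile normalization 3469, 1925 higher and 1544 lower, with 2225 called in both. Without Treg acetate replicate 1 there were 1484 calls.

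The calls of the subsets, which share no arrays but share 1 estimate of each gene's spread, overlapped. A gene with a small spread is easier to call in every subset, so the counts by independence are a low baseline. Th17 and Treg cultures shared 113 genes called higher, where independent lists would give 10.8, and 202 called lower against 39.9, with 7 called in opposite directions. Th17 and Th1 cultures shared 78 higher (7.62 by independence), 31 lower (6.02) and 0 opposite, and Treg and Th1 cultures 48 higher (4.11), 18 lower (1.23) and 4 opposite. After quantile normalization Th17 and Treg cultures shared 458 higher (89.8 by independence) and 316 lower (51.4), Th17 and Th1 cultures 140 (26.4) and 125 (18.1), and Treg and Th1 cultures 105 (15.9) and 115 (11.4). In all 3 subsets 37 genes were called higher, among them the metallothionein gene Mt3 and the proton pump gene Atp6v0d2, and 13 lower, among them the carnosine synthase gene Carns1; these 3 genes kept their calls in every subset without any single array. Independent lists would give 0.18 and 0.16. After quantile normalization these counts were 91 and 89, against 1.86 and 0.98 by independence. Across genes, the log2 differences correlated at r = 0.60 between Th17 and Treg, 0.44 between Th17 and Th1, and 0.40 between Treg and Th1 cultures.

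**Figure D3:**
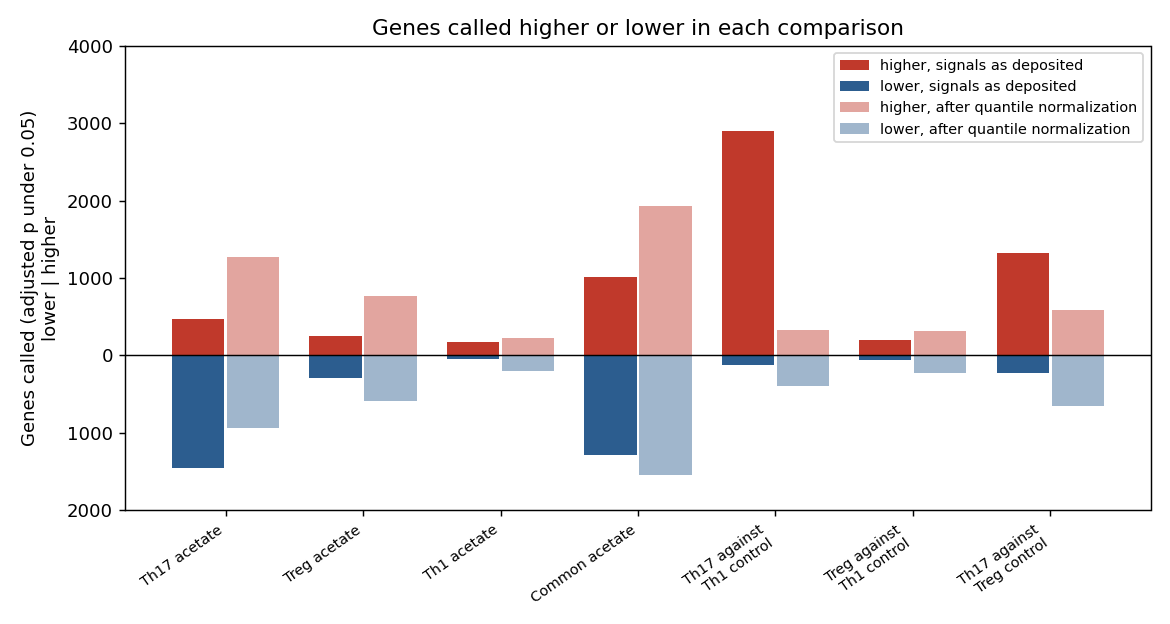
The number of genes called higher (red, up) or lower (blue, down) at an adjusted p under 0.05 is plotted for each comparison, with full colour for the signals as deposited and pale colour after quantile normalization. The split turns most for untreated Th17 against Th1 cultures, from 2906 higher and 119 lower to 326 higher and 395 lower.

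Whether the acetate effect differed between the subsets was tested with an F test in the same limma fit. Il24 rose by 6.15 ± 0.43 in Treg cultures, by 1.45 ± 0.35 in Th17 and had a difference of 0.11 ± 0.43 in Th1 cultures (adjusted p = 1.48e-05 for the difference between subsets). Its control signals were 12.1 and 20.8 in Treg, but 748 to 1068 in Th17 and 461 and 540 in Th1 arrays. The Treg acetate signals were 945 and 1914, so the subsets differed in their starting level. Ccl9 had differences of 6.41 in Th1, 2.31 in Treg and 1.25 in Th17 cultures (adjusted p = 0.0010; 0.10 with quantile normalization and the replicate block). The leukotriene receptor gene Cysltr1 had differences of -2.03 in Th17, 1.80 in Treg and -1.55 in Th1 cultures (adjusted p = 0.0014; 0.052 without Treg control replicate 2), and the actin regulator gene Enah had -1.97 in Th17, 1.57 in Treg and 0.30 in Th1 cultures (adjusted p = 0.0016). Bnip3, Egln3, Fcmr, Ms4a4c, Pdlim4 and Havcr2 differed at an adjusted p = 0.011 each. Foxp3 differed at an adjusted p = 0.042, with values of -2.70 in Th17, -2.55 in Treg and 0.09 in Th1 cultures, the last from a control signal of 10.9. Without 1 array, its adjusted p reached 0.12 for Treg control replicate 2, 0.11 for Th17 control replicate 1 and for Th1 control replicate 2, 0.098 and 0.059 for Treg acetate replicates 1 and 2, 0.077 for Th17 control replicate 3 and 0.076 for Treg control replicate 1. Without Treg control replicate 2 the adjusted p was 0.099 for Bnip3, 0.10 for Egln3, 0.083 for Fcmr, 0.063 for Ms4a4c and 0.052 for Pdlim4, and without Treg acetate replicate 1 it was 0.055, 0.067, 0.067, 0.053 and 0.053 for these and 0.053 for Havcr2. Without Th17 control replicate 1 it was 0.055 for Bnip3 and for Fcmr, 0.066 for Egln3 and 0.056 for Pdlim4.

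Ffar2 had an adjusted p = 0.051 for the difference between subsets, which fell under the threshold without Th17 acetate replicates 1 (0.019) and 3 (0.020), Th1 control replicate 1 (0.035) and Th1 acetate replicates 1 (8.6e-04) and 2 (0.018), and after quantile normalization (0.048). Il10 (0.12), Il17a (0.13), Ifng (0.32), Il2 (0.51), Tbx21 (0.54), Gata3 (0.74), Il4 (0.38), Acss1 (0.36) and Acss2 (0.72) did not pass. Il10 passed without Th17 acetate replicate 1 (0.019), Th1 control replicate 1 (4.9e-05) and Th1 acetate replicate 1 (0.023), Ifng without Th17 acetate replicate 1 (0.0042), Il2 without Th1 control replicate 1 (0.0079) and Il17a without Th1 acetate replicate 1 (0.049). Limma called 77 genes, and 87 after quantile normalization, 48 of them in both; 1641 had an unadjusted p under 0.05. The count was 15, 39 and 39 without Th17 control replicates 1, 2 and 3, 254 and 165 without Th17 acetate replicates 1 and 3, 41 and 4 without Treg control replicates 1 and 2, 5 and 37 without Treg acetate replicates 1 and 2, 277 without Th1 control replicate 1, and 503 and 127 without Th1 acetate replicates 1 and 2. For lists, the median over hypoxia genes of the Treg minus Th1 difference in acetate effect was 1.71 (camera adjusted p = 5.88e-18; adjusted p = 0.20 with an estimated correlation), and that over glycolysis genes 0.96 (adjusted p = 1.8e-15; adjusted p = 0.20 with an estimated correlation). The interferon response genes had a median Th17 minus Treg difference of 1.49 (adjusted p = 5.38e-13; adjusted p = 0.26 with an estimated correlation).

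**Figure D4:**
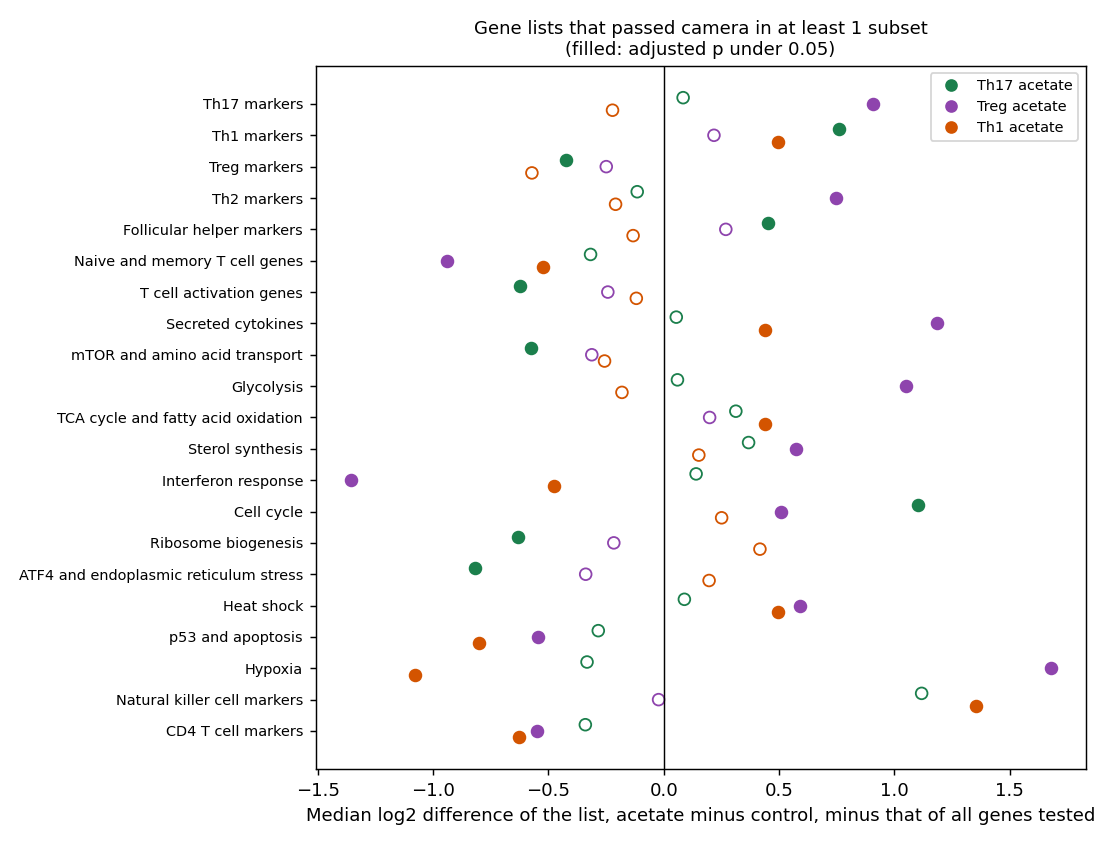
For each fixed list that passed camera in at least 1 subset, the median log2 difference of its members, acetate minus control, minus the median of all genes tested is plotted in Th17 (green), Treg (purple) and Th1 (orange) cultures; filled points passed at an adjusted p under 0.05. In Treg cultures hypoxia genes lie at 1.68 and interferon response genes at -1.36.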

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

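The F tests of single genes were planned, and the count of unnamed probe sets was chosen as a test only after the result was seen. The 10 genes with the smallest p for a difference of the acetate effect between subsets, and Foxp3 among the fixed lineage genes, are listed because that test passed. All log2 differences below are for Th17, Treg and Th1 cultures in this order, with limma's adjusted p.

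Il24, a cytokine gene of the IL-10 family, had differences of 1.45, 6.15 and 0.11 (adjusted p = 1.48e-05), and the chemokine gene Ccl9 of 1.25, 2.31 and 6.41 (adjusted p = 0.0010). Both passed without any single array. Il24 started from control signals of 12.1 and 20.8 in Treg, against 748 to 1068 in Th17 and 461 and 540 in Th1 arrays. Enah, an actin regulator gene, had -1.97, 1.57 and 0.30 (adjusted p = 0.0016), and the leukotriene receptor gene Cysltr1 -2.03, 1.80 and -1.55 (adjusted p = 0.0014, and 0.052 without Treg control replicate 2).

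The hypoxia genes Bnip3 and Egln3 had differences of 0.04, 2.66 and -0.84, and of -0.61, 2.43 and -0.80. Fcmr, the IgM receptor gene, had 0.15, 3.11 and -0.04, Ms4a4c 1.16, -2.74 and -0.56, Pdlim4 5.33, 0.79 and 2.86, and Havcr2, the gene of TIM-3, 0.59, -0.05 and 3.49. Each of these 6 had an adjusted p = 0.0108. Without Treg acetate replicate 1 it was 0.055 for Bnip3, 0.067 for Egln3, 0.067 for Fcmr and 0.053 for Ms4a4c, Pdlim4 and Havcr2. Without Treg control replicate 2 it was 0.099, 0.10, 0.083, 0.063 and 0.052 for the first 5, and without Th17 control replicate 1 it was 0.055 for Bnip3, 0.066 for Egln3, 0.055 for Fcmr and 0.056 for Pdlim4. After quantile normalization Havcr2 had an adjusted p of 0.053.

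Foxp3 had differences of -2.70, -2.55 and 0.09 (adjusted p = 0.0423). Its call was lost without Treg control replicate 2 (0.12), Th17 control replicate 1 (0.11), Th1 control replicate 2 (0.11), Treg acetate replicates 1 and 2 (0.098 and 0.059), Th17 control replicate 3 (0.077) and Treg control replicate 1 (0.076). In Th1 cultures its mean control signal was 10.9, near the level at which genes were left out.

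Probe sets without a gene name, which enter no comparison above, also differed between control and acetate arrays. Of 4436 such probe sets with enough signal, 114 were called higher and 464 lower for the mean acetate effect of the 3 subsets, and after quantile normalization 218 and 525.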

How the results depend on the processing

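The tests chosen only after the result was seen were scaling to the spiked-in controls, quantile normalization together with the replicate block or without the arrays next named, crossed Th1 numbers, and fits without Th17 acetate replicate 1 and Th1 acetate replicate 2, called the similar pair here. The cause of a change was not tested unless a setting tests fewer or other genes or arrays by its construction. Values are counts of calls unless said otherwise, and unlisted counts stayed within 1.5 times those reported.

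Quantile normalization gave 1363 calls for acetate in Treg and 435 in Th1 cultures, 3469 for the mean effect, and 721 for Th17 against Th1 and 545 for Treg against Th1 controls. Median scaling gave 936 for acetate in Treg cultures and 880 for Th17 against Th1 controls. Array weights, whose fit did not fully converge, gave 5634 (Th17 acetate), 1909 (Treg acetate), 3668 (mean effect), 5965 (Th17 against Th1), 458 (Treg against Th1), 4663 (Th17 against Treg) and 1234 (difference between subsets). Fits of only the groups compared gave 2161 for Treg acetate, 10 for Th1 acetate, 1505 for Th17 against Th1 and 772 for Treg against Th1. An adjusted p under 0.10 gave 849 (Treg acetate), 451 (Th1 acetate), 4619 (Th17 against Th1), 418 (Treg against Th1), 2490 (Th17 against Treg) and 205 (difference between subsets), and a log2 difference of at least 1 gave 715 (mean effect) and 1981 (Th17 against Th1). The mean of all probe sets gave 365, 107 and 38 for Treg acetate, Th1 acetate and the difference between subsets, and every probe set 3924 for the mean effect. Th1 acetate had 138 calls with no filter, 140 with the filter at the 60th percentile and 114 with eBayes without trend; the difference between subsets had 31 with no filter, 4 with eBayes without trend, 49 with a pseudocount of 1, 137 with one at the 50th percentile and 125 with scaling to the spiked-in controls.

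Without the similar pair there were 996 calls for Treg acetate, 648 for Treg against Th1 and 237 for the difference between subsets, and with quantile normalization as well 2179 (Treg acetate), 3700 (mean effect), 1507 (Th17 against Th1), 1148 (Treg against Th1) and 196 (difference between subsets).

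Whether replicate numbers pair control and acetate arrays is not stated and was not shown. After quantile normalization, deviations of same-numbered control and acetate arrays correlated at 0.15, 0.16 and -0.06 in Th17, 0.06 in Treg and -0.16 in Th1 cultures. Not every array correlated best with its own number. With the replicate block there were 1748 calls for Th17, 599 for Treg and 300 for Th1 acetate, 2158 for the mean effect and 239 for the difference between subsets; with quantile normalization as well, 957 for Treg acetate. Crossed Th1 numbers in the replicate block gave 378 calls for Th1 acetate.

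Without single arrays, counts ranged from 966 to 2798 (Th17 acetate), 109 to 738 (Treg acetate), 72 to 544 (Th1 acetate), 1484 to 2607 (mean effect), 486 to 5034 (Th17 against Th1), 72 to 428 (Treg against Th1), 336 to 2837 (Th17 against Treg) and 4 to 503 (difference between subsets).

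Signs turned for genes that were not called. Quantile normalization gave log2 differences of -0.10 for Acss2 in Th1 acetate (also with the replicate block), 0.23 for Ffar2 and 0.15 for Ifng in Th17 acetate (also with the block), 0.13 for Acss2 in Treg acetate (also with the block and without the similar pair), -0.41 for Acss2 in Th17 against Th1 (also without the pair) and -0.17 for Ffar2 in Th17 against Treg (also without the pair). Median scaling gave 0.11 for Ffar2 in Th17 acetate, 0.027 for Acss2 in Treg acetate, -0.13 for Acss2 in Th17 against Th1 and -0.064 for Ffar2 in Th17 against Treg. For Il2 in the mean effect, the pseudocount at the 50th percentile gave -0.026, and array weights and removal of the similar pair -0.029 each. For Acss2 the mean of all probe sets gave -0.30 in Th1 acetate and -0.017 in Th17 against Th1, and scaling to the spiked-in controls -0.042 in Th1 acetate. Array weights gave 0.18 for Acss1 in Th17 acetate and 0.064 for Gata3 in Th17 against Th1. Without the similar pair Ffar2 was 0.65 and Gata3 0.027 in Th1 acetate and Ffar2 0.10 in Th17 acetate; with quantile normalization as well, Ffar2 was 0.36 in Th1 and 0.30, and Acss1 0.051, in Th17 acetate. With fry the Th17 markers (adjusted p = 0.89) and secreted cytokines (adjusted p = 0.88) in Th17 acetate leaned lower, opposite to camera.

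Without single arrays the following spanned 0. For the mean effect, Acss2 ranged from -0.035 to 0.36, Cd8a from -0.0301 to 0.51 and Il2 from -0.55 to 0.76. For Th1 acetate, Acss1 ranged from -0.42 to 0.73, Acss2 from -0.53 to 0.65, Ffar2 from -0.97 to 0.65, Foxp3 from -0.0315 to 0.20, Gata3 from -1.73 to 0.027 and Il2 from -0.75 to 3.16. For Th17 acetate, Acss1 ranged from -0.54 to 0.18, Ffar2 from -0.30 to 0.10 and Ifng from -1.34 to 0.64. For Treg acetate, Acss2 ranged from -0.40 to 0.20, Il2 from -0.84 to 0.10, Il4 from -0.38 to 0.71 and Tbx21 from -0.42 to 0.016. In Th17 against Th1, Acss2 ranged from -0.35 to 0.83 and Gata3 from -0.43 to 0.40; in Th17 against Treg, Acss2 from -0.56 to 0.037 and Ifng from -1.39 to 0.19; in Treg against Th1, Acss2 from -0.084 to 1.09, Ifng from -1.44 to 0.58, Il10 from -0.67 to 2.86 and Il2 from -0.30 to 3.62. Of 66 genes followed in Th17 acetate 45 kept sign and call under every setting run gene by gene (not other thresholds, every probe set or fits of only the groups compared), as did 24 of 40 in Treg acetate, 11 of 34 in Th1 acetate and 47 of 56 for the mean effect.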

Other observations

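The gene families and cell markers in the next 2 paragraphs, and the tests of array brightness, of degraded RNA, of a swapped label and of different compounds further on, were chosen only after the result was seen; the other tests were written before.

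Members of some gene families were called in the mean acetate effect of the 3 subsets; the families were not tested for enrichment, and Gzmb also stands in the Th1 marker list. All 4 metallothioneins tested, small proteins that bind zinc and copper, were called higher: Mt3 by a log2 difference of 4.27 ± 0.32 (SE, adjusted p = 9.84e-09), Mt4 by 1.77, and the abundant Mt1 and Mt2 by 0.93 and 0.94. By subset, Mt4 was called only in Th1 cultures (4.70, against -0.12 in Th17 and 0.72 in Treg). Apart from Th1 acetate, every Mt4 group mean lay under 9.10. Mt1 and Mt2 were called only in Treg cultures (1.93 and 1.64). Of 8 granzymes and perforin, the proteins of cytotoxic granules, 7 were called higher, from 1.07 for Gzmb to 2.68 for Gzme, and Gzmf (0.70) did not pass. Among markers of cells that carry such granules, Klre1 (1.55) and Cd8b1 (1.04) were called higher as well, while Tyrobp (0.90, adjusted p = 0.052; 0.043 after quantile normalization, and 0.018, 0.049 and 0.013 without Th17 control replicate 2, Th1 control replicate 2 and Th1 acetate replicate 1), Cd8a (0.25) and Klrd1 (-0.40) did not pass, so a larger share of natural killer or CD8 T cells stays open. Of 14 glutathione S-transferases, which conjugate reactive compounds, 8 were higher, among them Gstm5 (2.50 ± 0.28), Gstt3 (1.77) and Gstm1 (1.60 ± 0.21), and Mgst2 was lower (-1.42). Of 11 tubulins 5 were higher, with Tubb2b at 1.67. In Th17, Treg and Th1 cultures the calls higher were 1, 3 and 2 for metallothioneins, 6, 1 and 4 for granzymes and perforin, 8, 4 and 3 for glutathione S-transferases and 3, 0 and 2 for tubulins; 1 glutathione S-transferase in Th17 and 1 tubulin in Treg cultures were lower. Quantile normalization, median scaling and scaling to the spiked-in controls left these families leaning the same way.

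Members of other families were called lower. Of 8 GTPases of immunity-associated proteins, which are linked to lymphocyte survival, 5 were called lower, among them Gimap3 (-1.52 ± 0.20, adjusted p = 1.11e-05) and Gimap5 (-1.11), and none higher. Of 6 Schlafen genes, which are linked to T cell quiescence and to interferon, 5 were lower, among them Slfn1 (-2.31), Slfn8 (-1.66) and Slfn2 (-1.56). In Th17, Treg and Th1 cultures the calls lower were 5, 3 and 1 for the GTPases, with a median of -0.08 in Th1, and 3, 3 and 0 for the Schlafen genes. Both directions were the same under quantile normalization, median scaling and scaling to the spiked-in controls.

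In Th17 cultures 75.8% of the calls were lower with acetate. Scan brightness as a cause was argued against, since scaling to the spiked-in controls left 80.6% of the calls lower. Removal of Th17 control replicate 1, the array with the highest signals, left 49.7% lower. Its spiked-in controls were also the highest, with a log2 deviation of 0.47, against -0.22 and -0.15 in Th17 control replicates 2 and 3. In Th17 acetate replicates 1, 2 and 3 this deviation was 0.07, -0.15 and 0.21. The removal used signals not scaled to these controls and kept the control arrays with the lowest deviations of the 6 Th17 arrays. It therefore cannot separate the scan brightness of Th17 control replicate 1 from its transcripts, nor tell whether the lean comes from that array. Median scaling gave 64.3% and quantile normalization 42.6%; both assume that most genes did not change, so a true fall of most transcripts in acetate stays open. For the count itself, 1928 in the real grouping, 1 of the 10 splits of the 6 Th17 arrays gave as many, namely the real one, and the highest other gave 0, but 10 splits are too few for a share under 0.05.

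After quantile normalization, Th17 acetate replicate 1 and Th1 acetate replicate 2 deviated from their groups alike, with r = 0.50 across genes. The Th1 acetate group has 2 arrays, so its replicate 1 deviated oppositely by construction (r = -0.50). Deviations given for Th1 are therefore differences between those 2 arrays, and which of them is unusual cannot be told. In Th17 acetate replicate 1 and Th1 acetate replicate 2, cell cycle genes (medians 1.51 and 0.94) and ribosome biogenesis genes (0.74 and 0.87) lay higher and hypoxia genes lower (-1.17 and -1.04). A stronger response of all genes was argued against, since their deviations correlated with the Treg acetate effect at 0.0153 and -0.0507, but one of part of the genes stays open, since both had the highest first principal component of their groups (38.4 and 37.9) and Mt3 above their groups (1.60 and 1.36). Degraded RNA was argued against by beta-actin 3-prime over 5-prime log2 ratios of 0.277 and 0.138, under the mean of the other acetate arrays (0.41, SD 0.05), although their Gapdh ratios of 0.11 and 0.07 lay within the range of the others (-0.01 to 0.13), and a swapped subset label by Il17a, at 4078 in the Th17 array against at most 13.5 in Th1 arrays, a ratio of 301 that is rough because so low a signal is imprecise. A shared gain of B cells, macrophages or dendritic cells, or CD8 T cells was argued against, since for each of these 3 marker lists the lower of the array medians was -0.449 or less. These lists held only 3, 4 and 2 genes tested. The test could not detect a loss, and the macrophage and dendritic cell markers were lower in both arrays (-0.81 and -0.62), so a shared loss of these cells stays open. Natural killer or gamma delta T cells may still differ, since natural killer markers (0.41 and 0.96), Xcl1 (3.12 and 2.35) and Trgv1 (1.96 and 1.76) were higher in both; the time of harvest or a shared batch was not tested.

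The acetate changes shared by the subsets could come from acetate or from something else common to the treated cultures. A chance split of the arrays was argued against for the count of the mean effect, 2303. Among 100 of the 360 possible splits within subsets, only 1, the real one, gave as many, and the highest other gave 623. A share of 1 in 100 is the smallest this test could give. It also treats arrays as independent, which nothing states, so chance differences between single cultures stay open. A metal load as the cause of the metallothionein rise was argued against by Slc30a1, a zinc exporter gene driven by the same metal sensor, at -1.78 (95% interval -2.45 to -1.10). Inhibition of histone deacetylases stays open: of 7 genes listed as its targets 5 were tested and 1, Clu (1.41), was higher, but Txnip (-0.86) was lower, and a median of -0.24 over members going both ways decides nothing, although it met the bound set beforehand. Different compounds, as the protocols read, cannot be told apart from differences between the subsets: the Treg and Th1 effects correlated at 0.404, below Th17 with Treg (0.53 to 0.59 over 9 choices of arrays) but within the range of Th17 with Th1 (0.29 to 0.51).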
